A study of Mus musculus with 3 samples.

How the data were processed

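Total RNA of sorted skin mast cells was extracted with TRIzol, and libraries were made and sequenced on an Illumina HiSeq by the Beijing Genomics Institute, per the labels' protocols. The authors deposited 1 table for the 3 libraries, holding FPKM values (fragments scaled to transcript length and to the mapped fragments of the library) per gene, per the file headers. The column of the early EMP library is headed as a control, and was matched to that library only through its description in the labels. The submitters' processing notes name Bowtie2, RSEM and the builds mm10 and GRCm38, with no versions. Values have 2 decimals. Of 17613 gene identifiers with a symbol, 17569 matched the RefSeq gene table of GRCm38.p6, from which coordinates come. The 3064 unnamed regions have no symbol; how they were defined, and from which libraries, is not given in the sources used here, so their number per library can depend on that. Because FPKM is a share, a few very abundant genes affect every other value, and a gene at 0 can be a failed estimate. Where near-identical copies exist, the estimate can move reads between them.

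Each library was the only one of its group: early EMP, late EMP and fetal HSC. The comparisons, gene lists, thresholds, naming rule and alternatives were fixed before the data were examined, except where stated. No test could be made with 1 library per group, so no p-value is given. Genes with at least 1 FPKM in at least 1 library were kept, 14412 of 20677. Fold changes are log2((FPKM + 1) / (FPKM + 1)), which understates the change of low genes; genes at least 2-fold apart were counted, with 4-fold as a stricter level. Depth is not stated. It was implied from the steps between low values of genes with 1 transcript, where 65.8%, 70.3% and 60.1% of values lay within 0.15 of a whole number of fragments. The step and a length offset were chosen to fit these same values best, within a set range. For a step fixed beforehand 30% would do so by chance, which understates chance for a fitted one. The depth is therefore an imprecise estimate. Counting noise was drawn 20 times from that depth, and covers counting error only.

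Each of 51 gene lists was described by its median log2 fold change among its measured members with a symbol, and by that median's percentile among 10000 random lists of the same size matched on mean expression in 20 bins. This describes these libraries and is not a test. Of 150 medians, 58 lay outside the 2.5th to 97.5th percentile. On simulated data 9 of 100 unshifted lists of 20 genes did. Those lists were random genes, and apart from the changed genes the simulated libraries differed by counting noise only. The simulation therefore gives no rate to set against the 58. The steps were tested on simulated data: 200 of 200 genes changed 4-fold were found among 14412 genes. The changed genes were drawn only from those with a mean of 5 FPKM or more. Of lists shifted by 1 on the log2 scale, 100 of 100 lay above the 97.5th percentile. With changes this large, these checks show that the steps run, not how well smaller changes or lower genes are found.

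Named genes followed a rule: the 10 largest in each direction per comparison among genes at 10 FPKM or more in 1 library and above 0 in both, leaving out predicted genes; up to 4 per direction listed at 0 in 1 library; the 2 most abundant and up to 4 most different members per list at 5 FPKM or more; and Csf1r, Runx1, Kit, Fcer1a, the connective tissue proteases and sex-linked genes. Not every gene the rule allows is named. A list gene too low for it may be named with its values. Alternatives were pseudocounts of 0.1 and 5 FPKM, no filter and a filter at 5 FPKM, rescaling to the same total, median-of-ratios factors, rescaling without the 50 most abundant genes, and Spearman's rho. Leaving out the unnamed regions was added after the data were seen. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.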

Results

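RNA was measured in skin mast cells sorted from mice 1 week after birth, in 3 libraries that differ in the embryonic origin of the labelled cells. The cells carried the yellow fluorescent protein EYFP after a pulse of 4-hydroxytamoxifen, the drug that switches on an inducible Cre recombinase. A pulse at embryonic day 8.5 in mice with Csf1r-driven Cre gave the library labelled early erythro-myeloid progenitor (early EMP). With Runx1-driven Cre, a pulse at day 8.5 gave the library labelled late EMP, and a pulse at day 9.5 gave the library labelled fetal haematopoietic stem cell (fetal HSC). Each origin has 1 library, so no difference given here has a replicate check, and no p-value is given. The driver line differs between the early EMP library and the other 2, and that difference cannot be separated from origin. The table lists 20677 genes, of which 17613 have a symbol and 3064 are unnamed transcribed regions. The deposited FPKM values sum to 639067 in the early EMP library, 614207 in the late EMP library and 640500 in the fetal HSC library. From the steps between low values, the implied depth was 15.6, 15.6 and 17.2 M fragments, in the same order.

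All 3 libraries were dominated by the granule proteases of connective tissue mast cells. Cma1, a chymase (chromosome 14, 55941451 to 55944675, GRCm38), was at 73918 FPKM in the early EMP library, 63894 in the late EMP library and 80925 in the fetal HSC library. The tryptase Tpsb2 was at 79281, 62101 and 62828 FPKM, and the carboxypeptidase Cpa3 at 38942, 37222 and 53824 FPKM. The 10 most abundant genes took 39.2%, 34.8% and 39.1% of the summed FPKM. Of the 7 connective tissue protease genes, 6 lay within 2-fold between late and early EMP and 5 between fetal HSC and early EMP. Ctsg, cathepsin G, was at least 2-fold higher in both other libraries, at 753 and 783 FPKM against 112 in the early EMP library. The list medians were -0.21, -0.23 and 0.06 on the log2 scale for late over early EMP, fetal HSC over early EMP and fetal HSC over late EMP.

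Most genes of mast cell identity and activation lay within 2-fold. Kit, the stem cell factor receptor, was at 414, 606 and 405 FPKM, and Fcer1a, a chain of the IgE receptor, at 38.8, 59.0 and 52.0 FPKM. Among 20 measured surface receptors, 17 lay within 2-fold in each comparison with early EMP and all 20 between fetal HSC and late EMP, with medians of 0.00, 0.00 and -0.12. The 17 genes of IgE receptor signalling had medians of -0.28 and -0.35 in the comparisons with early EMP, at percentiles 0.23 and 0.58 of matched random lists, and -0.02 between the late EMP and fetal HSC libraries. Lat, an adaptor of that pathway, was at 136, 59.9 and 77.2 FPKM. Mast cell transcription factors had medians of 0.08, -0.06 and -0.12, and Gata2 was at 664, 517 and 359 FPKM. The degranulation machinery had medians of 0.06, 0.01 and -0.01. The 14 measured genes of histamine, serotonin and heparin synthesis had medians of 0.04, -0.28 and -0.42, at percentiles 41.7, 1.83 and 0.07 of matched lists; with the filter at 5 FPKM the second was at 2.87. Slc6a4, the serotonin transporter, was at 591, 379 and 277 FPKM, while Hdc, which makes histamine, was at 3614, 3061 and 3069 FPKM. Lysosome and granule membrane genes had medians of 0.03, -0.20 and -0.19, at percentiles 38.3, 1.71 and 2.64, with no member beyond 2-fold. Mrgpr receptors had medians of 0.42, -0.26 and -0.28, and the receptor Mrgprb2 was at 902, 802 and 755 FPKM and Mrgpra6 at 135, 181 and 39.1.

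The recombinase driver genes were read in each library because they name the lines. Csf1r was at 5.70, 2.54 and 1.47 FPKM in the early EMP, late EMP and fetal HSC libraries, and Runx1 at 12.7, 12.3 and 12.5 FPKM; their list medians were -0.48, -0.73 and -0.25. Sex-linked RNAs also differed. Xist, transcribed from the inactive X chromosome, was at 25.6, 0.53 and 52.0 FPKM. The Y-linked Ddx3y was at 20.7, 38.5 and 0.32 FPKM, and Eif2s3y at 24.6, 44.3 and 0.35 FPKM. The 5 sex-linked genes had medians of 0.83, -1.47 and -2.75. The early EMP library thus held RNAs of both sexes, and sex-linked RNA differed with origin in every comparison; the sex and number of animals are not given in the sources used here.

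Late EMP over early EMP asks how mast cells labelled by the later progenitor wave differ from those labelled by the earlier one. Genes of cell division were higher in the late EMP library: 19 of 20 mitosis genes were at least 2-fold higher and none lower, with a median of 1.74 on the log2 scale, above every matched random list (percentile 100). Birc5, a survivin protein of the mitotic spindle, was at 33.7 FPKM against 4.11, and Ube2c, which tags mitotic proteins for degradation, at 35.1 against 3.55. Of 19 DNA replication genes, 13 were higher and none lower (median 1.33, percentile 100), among them the helicase subunit Mcm6 at 53.9 FPKM against 13.1. Among the largest differences were those of Cd200r4, an activating receptor (107 FPKM against 1.11, log2 5.68), Pcp4l1 (86.3 against 2.09, log2 4.82), S100a4 (83.2 against 2.11, log2 4.76), Arg1, the arginase of the urea cycle (33.0 against 0.29, log2 4.72), Mpo, the myeloperoxidase of granulocyte precursors (39.2 against 0.88, log2 4.42) and Cxcr6, a chemokine receptor (23.1 against 0.48, log2 4.02).

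Other groups were also higher in the late EMP library. Cholesterol synthesis genes had 5 of 17 members higher and none lower (median 0.80, percentile 100), with Fdps, which makes farnesyl diphosphate, at 29.1 FPKM against 12.9. Cytokines had 5 of 17 higher (median 0.43, percentile 99.3, and 92.58 with a pseudocount of 5 FPKM), including Il6 at 78.3 FPKM against 23.2 and Csf2, which encodes GM-CSF, at 64.7 against 26.5. The T cell and innate lymphoid list had 5 of 11 higher and 1 lower (median 0.96), with the costimulator Icos at 21.6 FPKM against 9.42, while the T cell receptor component Cd3e was listed at 0 against 13.5. MHC class II genes had 4 of 9 higher (median 0.82, percentile 99.95). The melanocyte list had 4 of 5 higher (median 1.69), with Pmel at 6.40 FPKM against 1.05. Heat shock genes had 4 of 11 higher (median 0.41), with Hspa8 at 1460 FPKM against 724. Eicosanoid synthesis genes had 2 of 10 higher (median 0.65), and integrins and homing receptors 6 of 21 (median 0.38, percentile 99.55, and 93.95 with the filter at 5 FPKM). Mucosal mast cell genes had 2 of 5 higher, but their median of 0.49 lay within the range of matched lists (percentile 96.5, and 98.36 with a pseudocount of 5 FPKM). In the other direction, the erythroid list had 5 of 11 lower and 4 higher (median -0.59). Its lower members were the haemoglobin genes Hba-a1 (7.95 FPKM against 124), Hba-a2, Hbb-bs, Hbb-b1 and Hbb-b2, while Hbb-bt was at 2.77 against 4.66, under 2-fold. Its higher members were Car1, Car2, Klf1 and Ahsp. Chemokines had 5 of 16 lower and 3 higher (median -0.43), with Ccl7 at 3406 FPKM against 8661; Ccl2 was at 2013 against 3702, under 2-fold. Fbp2 (4.04 FPKM against 87.0) and Zfp949 (5.12 against 93.7) were among the lowest.

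In total 2798 of 14412 genes were at least 2-fold apart, 1245 higher and 1553 lower in the late EMP library. Without the unnamed regions, 1356 of 11529 were, 868 higher and 488 lower, a restriction chosen after the data were seen. Counting noise drawn from the implied depth gave a median of 1.5 genes against 1303 observed among 11339 genes with a known length, but it does not include variation between animals or preparations. Pearson's r across genes, which are not independent replicates, was 0.926.

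Fetal HSC over early EMP asks how the mast cells labelled at day 9.5 differ from those labelled by Csf1r-driven Cre. The genes of antigen presentation by MHC class II were the group with the largest median among those with over 5 measured members: 5 of 9 were at least 2-fold higher and none lower, with a median of 2.48 (percentile 100). Smaller lists had larger medians: melanocyte markers 2.65 over 5 measured genes and neutrophil markers 4.65 over 3. H2-Ab1 (chromosome 17, 34263227 to 34269418, GRCm38) was at 541 FPKM against 9.11, H2-Aa at 111 against 1.87, and Cd74, the invariant chain (chromosome 18, 60803849 to 60812652), at 639 against 12.9. Mitosis genes had 18 of 20 higher and none lower (median 1.82, percentile 100), with Birc5 at 42.7 FPKM against 4.11. DNA replication genes had 10 of 19 higher (median 1.05). Cd200r4 was at 180 FPKM against 1.11 (log2 6.42), Mpo at 47.9 against 0.88, Elane, the neutrophil elastase, at 34.7 against 0.42, and Lsp1, a leukocyte actin-binding protein, at 41.5 against 0.74.

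Genes lower in the fetal HSC library than in the early EMP library included the Klra family of lectin-like receptors, which summed to 1.27 FPKM against 372, and Mgl2, a C-type lectin, at 4.38 FPKM against 231. Klra members are near-identical and their single values are uncertain. A split of reads among them would leave their sum largely unchanged. The sum was 93.0 FPKM in the late EMP library, and the cause of its difference was not tested. The macrophage list had 7 of 15 members lower and none higher (median -0.996, percentile 0), with C1qa at 3.05 FPKM against 14.8 and C1qb at 3.96 against 20.4, while Lyz2 was at 44.8 against 37.7. The erythroid list had 6 of 11 lower and 3 higher (median -2.44), and the megakaryocyte and platelet list 4 of 6 lower (median -1.10), with Pf4 at 7.05 FPKM against 46.7. Circadian clock genes had 5 of 12 lower (median -0.65), with Arntl at 1.46 FPKM against 5.30. Of the T cell and innate lymphoid list 6 of 11 were higher and 1 lower (median 1.16), and of the melanocyte list 4 of 5 were higher (median 2.65). The unfolded protein response had 3 of 15 higher (median 0.78), with Hspa5, its chaperone, at 671 FPKM against 275; for late over early EMP its median was 0.61 at percentile 99.98. Lists described above for late over early EMP had medians here of 0.69 for cholesterol synthesis (percentile 100), 0.35 for cytokines (98.74), 0.45 for eicosanoid synthesis (98.83), 0.50 for mucosal mast cell genes (96.92), 0.24 for heat shock genes (90.59) and 0.25 for integrins and homing receptors (96.36, and 99.15 with a pseudocount of 5 FPKM). Chemokines had a median of 0.22 (percentile 90.7), which turned to -0.34 with the filter at 5 FPKM. The 3 measured genes of the neutrophil list were all higher (median 4.65).

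In total 3745 of 14412 genes were at least 2-fold apart, 1179 higher and 2566 lower in the fetal HSC library. Without the unnamed regions the numbers were 1919 of 11529, with 929 higher and 990 lower. Counting noise gave a median of 1 gene against 1855 observed. Pearson's r across genes was 0.911.

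Fetal HSC over late EMP compares the 2 libraries made with the same Runx1-driven Cre. These libraries carry opposite sex-linked RNAs, with Xist at 52.0 FPKM against 0.53 and Ddx3y at 0.32 against 38.5. With 1 library each, a difference between them cannot be separated from the sex of the animals. MHC class II genes had the largest median among lists with over 5 measured members: 7 of 9 were at least 2-fold higher in the fetal HSC library and none lower (median 1.66, percentile 100). H2-Ab1 was at 541 FPKM against 63.2 and Cd74 at 639 against 84.8. Among smaller lists, the 5 sex-linked genes were all beyond 2-fold (median -2.75), and of the 3 measured neutrophil genes 2 were higher (median 1.88), with Elane at 34.7 FPKM against 8.73 and S100a8 at 29.0 against a listed 0. The melanocyte list had 2 of 5 higher and none lower (median 0.82, percentile 99.78), with Mlana at 17.6 FPKM against 2.23. Chemokines had 3 of 16 higher (median 0.64, percentile 100), with Cxcl10, an interferon-induced chemokine, at 9.03 FPKM against 1.85 and Ccl6 at 2.76 against 0.15; Ccl4 was at 508 against 265, under 2-fold. Dnase1l3, an extracellular nuclease, was at 12.4 FPKM against 0.63, Npy, a neuropeptide, at 19.5 against 1.63, Plbd1 at 26.0 against 2.47, and Ifi205 at 18.2 against 1.11. Mitosis genes did not separate these libraries: none of 20 passed 2-fold (median 0.11), nor did more than 1 of 19 DNA replication genes (median -0.21). Macrophage genes were lower, 6 of 15 (median -0.64), as were 3 of 6 platelet genes (median -0.82). Mgl2 was at 4.38 FPKM against 72.0, and Pde6h at 0.62 against 14.6. In total 1686 genes were at least 2-fold apart, 496 higher and 1190 lower, or 930 without the unnamed regions, with 313 higher and 617 lower. Counting noise gave a median of 1.5 genes against 877 observed. Pearson's r across genes was 0.954.

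**Figure D1:**
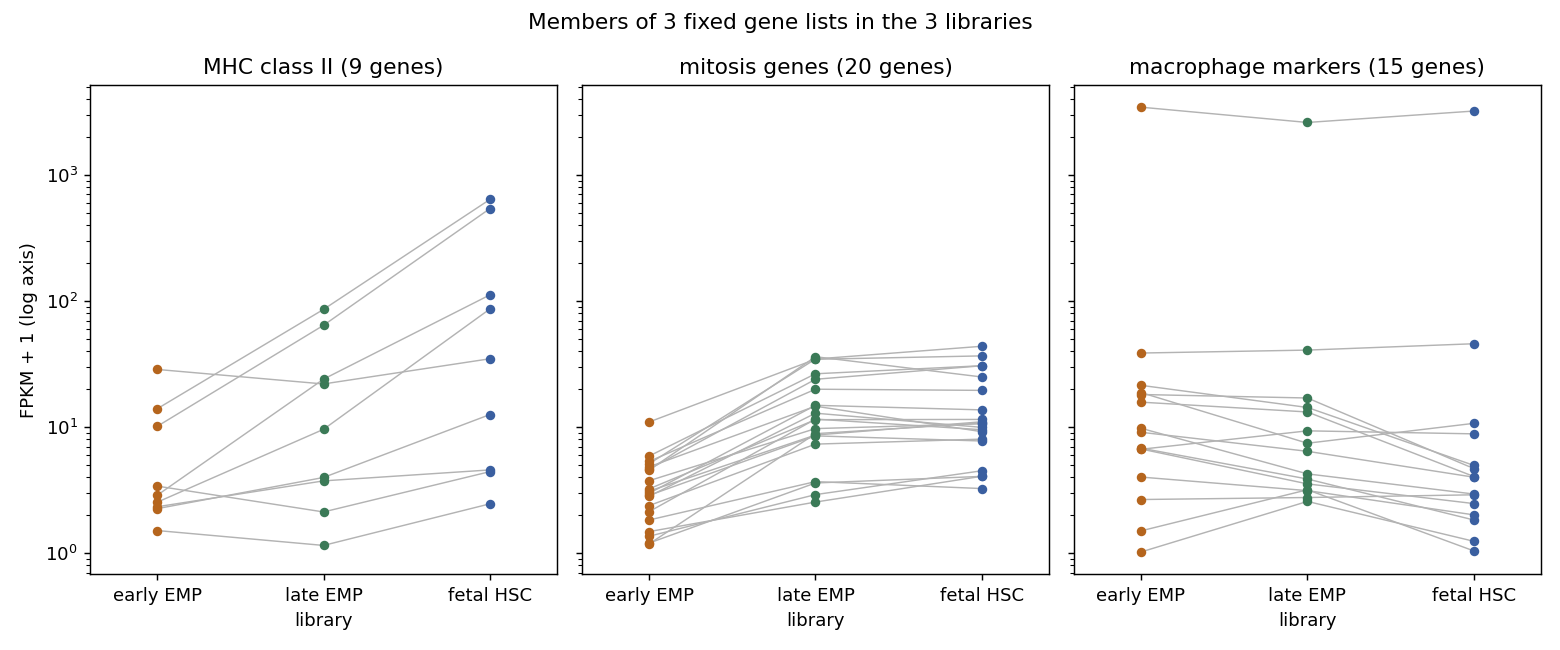
FPKM plus 1 (log axis) of each measured member of 3 fixed gene lists in the early EMP, late EMP and fetal HSC libraries, 1 library each; points are genes and grey lines join the same gene. Cd74 and H2-Ab1 are highest in the fetal HSC library (639 and 541 FPKM), the mitosis genes are lowest in the early EMP library, and 7 of 15 macrophage genes are at least 2-fold lower in the fetal HSC library than in the early EMP library.

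The early EMP library stood furthest from the others. Among genes with a symbol, 758 were at least 2-fold apart from both other libraries, 303 higher and 455 lower. The late EMP library had 210 such genes and the fetal HSC library 447. Counting all genes, the numbers were 1753, 536 and 751. The unnamed regions at 1 FPKM or more numbered 2130 in the early EMP library, 1074 in the late EMP library and 765 in the fetal HSC library.

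**Figure D2:**
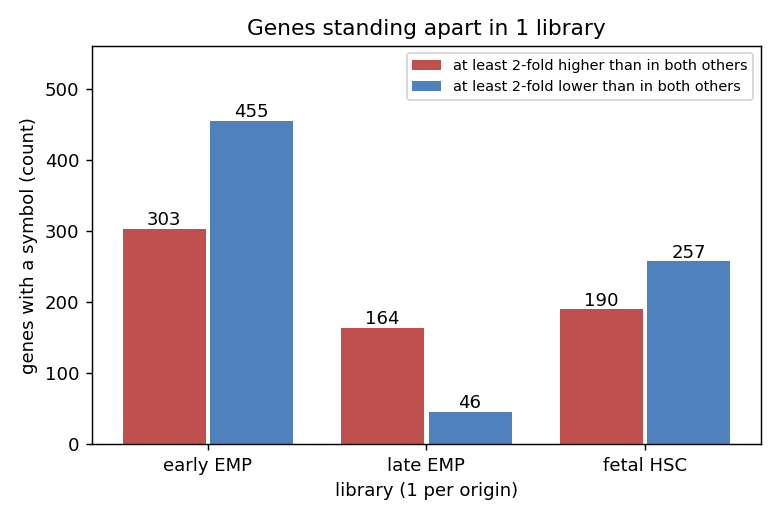
Number of genes with a symbol that were at least 2-fold higher (red) or lower (blue) in 1 library than in both others, for the early EMP, late EMP and fetal HSC libraries, 1 library each. The early EMP library has 303 and 455, the late EMP library 164 and 46, and the fetal HSC library 190 and 257.

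Medians of the remaining lists follow in the order late over early EMP, fetal HSC over early EMP and fetal HSC over late EMP. Ribosomal proteins had medians of 0.26, 0.23 and -0.12 over 75 genes, at percentiles 100, 99.85 and 0.01, with 72, 68 and 72 genes within 2-fold. Members with near-identical copies have uncertain single values. Rpl34 was at 113, 207 and 323 FPKM, but with its copy Rpl34-ps1 summed to 326, 347 and 331. Rps27 was at 933, 831 and 383 FPKM, while its family summed to 1075, 986 and 910. How far such splits of reads set these percentiles was not tested. Oxidative phosphorylation had -0.01, 0.04 and 0.04, with none of 30 beyond 2-fold. Housekeeping genes had 0.21, 0.20 and 0.01, and Gapdh, the exception, was at 68.9, 295 and 287 FPKM. NF-kB feedback genes had 0.49, 0.49 and -0.01, at percentiles 99.78, 99.75 and 55.3; Nfkbia, an inhibitor of that pathway, was at 1116, 1865 and 1959 FPKM. Immediate early genes had 0.27, 0.00 and -0.17 (percentiles 98.25, 28.8 and 1.77), glycolysis and hypoxia genes 0.33, 0.01 and -0.16 (percentiles 98.3, 42.3 and 9.43), and the type I interferon response -0.04, -0.25 and 0.01. With the filter at 5 FPKM, late over early EMP moved to a median of 0.25 at percentile 97.36 for immediate early genes and 0.20 at percentile 86.06 for glycolysis and hypoxia genes, inside the bounds. With that filter the type I interferon response turned to 0.03 and 0.04 in the comparisons with early EMP. MHC class I genes had 0.17, -0.02 and 0.00, and pattern recognition receptors -0.11, 0.00 and -0.21. Haematopoietic progenitor genes had 0.33, which turned to -0.09 with the filter at 5 FPKM, 0.11 and 0.12, and fetal and oncofetal genes 0.11, 0.24 and 0.17.

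Markers of other cell types were read as a check of the sort. Basophil markers had medians of 0.21, 0.46 and 0.32 (percentiles 77.2, 98.19, or 96.21 with a pseudocount of 5 FPKM, and 98.94), eosinophil markers 0.71, 0.35 and -0.36, and dendritic and Langerhans cell markers 0.56, 0.40 and 0.61 (percentiles 92.5, 86.8 and 98.63). With a pseudocount of 0.1 FPKM the dendritic medians over early EMP were 2.02 and 1.71, at percentiles 99.05 and 98.15, and with 5 FPKM the third was 0.21 at percentile 96.2. B cell markers had 0.45, 0.65 and 0.15, and NK cell markers 0.00, 1.45 and 1.39 over 3 genes. Of these, Nkg7 was at 112, 117 and 308 FPKM, Klrk1 at 0.60, 0.47 and 1.51, and Gzma was listed at 0 in both EMP libraries and at 2.31 in the fetal HSC library. Fibroblast markers had 1.19, 0.71 and -0.56, all at 3.57 FPKM or less. Keratinocyte markers had 0.59, -0.01 and -0.68, endothelial markers 0.41, -0.37 and -0.54, Schwann cell and nerve markers 0.25, -0.06 and -0.22, pericyte and smooth muscle markers -0.19, -0.32 and -0.13, and skeletal muscle markers -0.49, -0.68 and -0.19. With the filter at 5 FPKM, keratinocyte markers turned to -0.20 for late over early EMP, and for fetal HSC over early EMP endothelial markers turned to 0.30 and Schwann cell and nerve markers to 0.16. With a pseudocount of 5 FPKM, pericyte and smooth muscle markers turned to 0.05 and 0.00 over early EMP. The adipocyte list had 1 measured gene, Fabp4, at 1.55, 0.39 and 0.81 FPKM. These lists had few measured members, and a bulk library does not assign RNA to cells.

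Values of genes with near-identical copies are uncertain, since reads can be split between the copies; no test was made of whether this sets the differences. Ndufs5 was listed at 0 in the early EMP library and at 37.5 and 42.5 FPKM in the others, while BC002163, which the reference names as its pseudogene, was at 85.0 FPKM in the early EMP library and listed at 0 in the others. Atp6v0c-ps2 was at 0.45, 48.3 and 0.29 FPKM, with Atp6v0c included 254, 252 and 200. Tmem254b was at 27.3, 65.3 and 0.06 FPKM, and the Tmem254 copies together at 27.5, 70.7 and 67.8. Rps27rt was listed at 0 in both EMP libraries and at 369 FPKM in the fetal HSC library, while the Rps27 family summed to 1075, 986 and 910. H2-L was at 75.1, 197 and 1.05 FPKM, and with H2-D1 summed to 918, 1348 and 664, so the sum differed as well. A split of reads between these genes would not by itself change the sum. Whether the animals of the libraries differed in MHC haplotype was not tested.

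**Figure D3:**
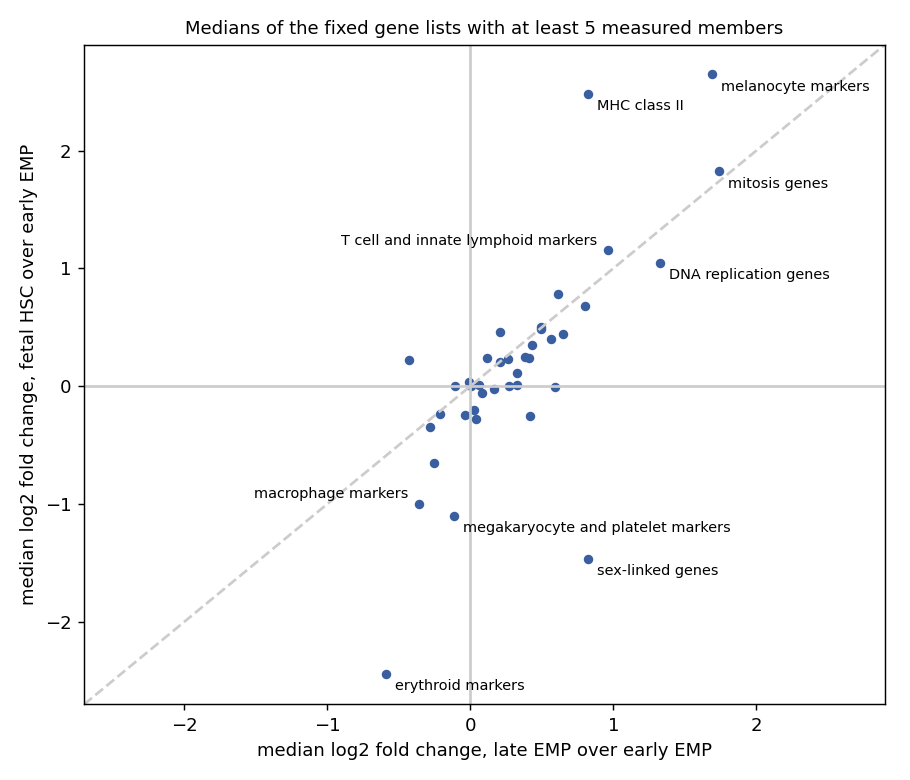
Median log2 fold change of 40 fixed gene lists with at least 5 measured members, late EMP over early EMP (x axis) against fetal HSC over early EMP (y axis), with 9 lists named; the dashed line marks equal values. Both axes share the early EMP library, so points along the line are partly expected. MHC class II lies at 0.82 and 2.48, mitosis genes at 1.74 and 1.82.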

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

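The restriction to genes with a symbol was chosen after the data were seen; the other alternatives were planned. No paired analysis was possible because each group has 1 library. With a pseudocount of 0.1 FPKM, 4522 genes were 2-fold apart for late over early EMP and 3615 for fetal HSC over late EMP; 3228, 1142 and 2321 stood apart in the early EMP, late EMP and fetal HSC libraries; and Pearson's r was 0.823 (late and early EMP), 0.806 (fetal HSC and early EMP) and 0.903 (fetal HSC and late EMP). With 5 FPKM, 328, 460 and 195 genes were 2-fold apart for late over early EMP, fetal HSC over early EMP and fetal HSC over late EMP, and 187, 34 and 106 stood apart. With at least 5 FPKM in a library, the counts were 766, 1097 and 524, and 473, 104 and 297 stood apart, since fewer genes are tested. Rescaling to the same total set each library to 1 M and left the pseudocount at 1. All values rose, so the pseudocount weighed less. With it 2284, 746 and 1168 genes stood apart in the early EMP, late EMP and fetal HSC libraries. The main counts were 1753, 536 and 751. With only genes with a symbol, 1356, 1919 and 930 were 2-fold apart and 758, 210 and 447 stood apart. The share of higher genes for late over early EMP was 44.5%, and 64.3% with a pseudocount of 5 FPKM or 64.2% with the filter at 5 FPKM; for fetal HSC over early EMP it was 31.5%, 55.2% and 48.0%. Scaling moved the median of all genes by under 0.1. With the filter at 5 FPKM, only 54 of the 58 list medians outside the percentile bounds and 75 of the other 92 had a value. Where they had one, none of the 58 changed sign, and 26 of the 92 did under at least 1 alternative. A pseudocount cannot change the sign of a single gene's fold change, and scaling moved values little. Most of this stability was therefore fixed in advance. The filter at 5 FPKM could more readily turn a median, and it turned none of the 54. Of the list medians, 141 of 150 with a pseudocount of 5 FPKM and 145 with 0.1 FPKM stayed on their side of the percentile bounds, as did 149 under each of the rescaling to the same total and the median-of-ratios factors, and 123 of those with a value with the filter at 5 FPKM, where 5 moved inside the bounds and 1 outside.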

Other observations

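All tests reported here were chosen after the result was seen, except those on further dendritic cell genes and on sensory receptor genes at 0.2 FPKM. Among genes that no comparison above described, the chemokine receptors Ccr2 and Ccr1 were at 0.11, 5.56 and 6.66 FPKM and at 0.48, 2.28 and 6.17 FPKM in the early EMP, late EMP and fetal HSC libraries. The cytokine Il5 was at 0.56, 13.1 and 32.3 FPKM, and Areg, which encodes amphiregulin, at 0.06, 4.94 and 5.83. Prss34, a basophil and mast cell protease, was at 2386, 459 and 989 FPKM, and the mucosal protease Mcpt2 at 7.62, 35.2 and 60.1. Bst2 was at 11.8, 35.6 and 60.1 FPKM while Ifitm3 was at 13.01, 17.9 and 5.67.

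MHC class II genes were highest in the fetal HSC library. The macrophage list had a median of -0.996 for fetal HSC over early EMP, with 7 of 15 members lower and none higher. That argues against more macrophages carrying these markers as a set. A net fall cannot exclude a few macrophages of another kind. An MHC haplotype of the animals does not reach Cd74, on another chromosome, whose log2 fold change was 5.52. Cd74 does not speak for the genes inside the MHC. There H2-L, an MHC class I gene, was at 75.1, 197 and 1.05 FPKM, and whether haplotypes differed was not tested. Admixed dendritic cells stay open. For fetal HSC over early EMP, 18 further dendritic cell genes, of which 11 were measured, had a median of 0.77 at percentile 99.86. Of these, 5 were at least 2-fold higher and 2 lower. By the rule set beforehand, that result went with admixed dendritic cells. Among the higher members, Naaa was at 4.19, 6.68 and 21.3 FPKM and Cst3 at 413, 531 and 970. The other higher members were low in the fetal HSC library: Rab7b at 3.03, Cd24a at 4.97 and Tnni2 at 7.80 FPKM. The lower members were Gcsam at 109, 57.3 and 53.8 and Cadm1 at 23.5, 9.29 and 9.78. The cells were sorted as mast cells, and the gate is not given in the sources used here. For fetal HSC over late EMP, these dendritic cell genes had a median of 0.66 at percentile 99.99, with 3 at least 2-fold higher and 2 lower. For late over early EMP their median was 0.36 at percentile 93.11, with 2 higher and 1 lower. The planned dendritic and Langerhans cell list lay inside the bounds for fetal HSC over early EMP. Its median was 0.40 at percentile 86.76, or 98.15 with a pseudocount of 0.1 FPKM, with 2 of 5 higher and none lower. Its member Clec10a was at 440, 285 and 280 FPKM. For fetal HSC over late EMP that list was at percentile 98.63. Whether mast cells themselves carry the MHC class II RNA, in relation to origin, was not tested.

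Mitosis genes were lowest in the early EMP library. Lower values of moderately expressed genes overall would leave matched lists as high, but the list was at percentile 100 for late over early EMP. That percentile is the one given above, so it is no further evidence. It speaks only to a shift shared by genes of like mean expression. Sex of the animals is argued against by the late EMP and fetal HSC libraries, which carry opposite sex-linked RNAs and differed by a median of 0.11. Admixed cycling cells of another type cannot be told apart from cycling mast cells, since a bulk library does not assign RNA to cells. For late over early EMP, 2 of the 3 measured neutrophil genes were at least 2-fold higher and 1 lower (median 2.78, percentile 100). Mpo had a log2 fold change of 4.42 and Elane of 2.78. The lower gene, S100a8, was at 1.30 FPKM in the early EMP library and listed at 0 in the late EMP library. Origin and driver line remain open.

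Unnamed transcribed regions were most numerous in the early EMP library. Genomic DNA would raise sensory receptor genes, and the values go both ways. At 0.2 FPKM or more, the level set beforehand, 88 of 379 such genes were listed there, against 137 in the late EMP library and 36 in the fetal HSC library, a ratio of 0.642 to the higher of these. By the rule set beforehand, that result went against genomic DNA. At 1 FPKM, the level at which the regions are counted, the numbers were 22, 13 and 10, a ratio of 1.69. This level was added after the result was seen. Since the levels disagree, genomic DNA stays open. Greater depth is argued against by an implied depth 0.907 times that of the deepest library, as far as that imprecise fit holds. No biological explanation was tested. From which libraries the regions were defined is not given in the sources used here, which leaves the authors' definition open too.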
